A study of Drosophila melanogaster with 18 samples.

How the data were processed

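RNA was measured by poly(A) RNA-seq in dissected pupal wings of Drosophila melanogaster, with at least 40 wings per sample, at 24 h and 44 h after puparium formation. Per the labels, the flies carried the rotund driver rn-Gal4 alone (control), with an E93 RNAi transgene (E93RNAi) or with E93 and br RNAi transgenes together (E93RNAi+brRNAi). Each of the 6 groups had 3 libraries, so 18 libraries entered the comparisons, and no library from flies with the br transgene alone was analysed here. Nothing in the labels says that the libraries of a group came from separate crosses or days, so p-values measure only the spread between these libraries, which may be technical.

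The deposited values are of 2 kinds and were made by the authors. The first is a count of reads per gene, whole numbers without normalization. The second is cRPKM, which the deposited values show to be an RPKM, the count scaled by the library total and by a length of the gene. That length was the same in every library to within 0.13% (coefficient of variation) over 3590 genes with more than 500 counts in every library. For 92% of 5698 genes with more than 5000 counts over all libraries, that length was within 1 base of an annotated transcript length less 49 bases. The submitters' processing notes name the dm6 build. The aligner, the counter and whether counting used the strand are not given in the sources used here. The library kit keeps the strand, but reads of overlapping and antisense genes cannot be taken as separated, and near-identical paralogs may share reads.

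Each deposited table listed 14489 genes, of which 758 had no value in any library and 13731 had values. Of these, 13510 identifiers were matched to a symbol in the Ensembl release 115 annotation of BDGP6, whose coordinates are given, and 221 were not. Among the unmatched features, FBgn0000210 was taken as br, on the following grounds. It is a former FlyBase identifier of br, from background knowledge. Its implied length of 8173 bases is within 2 bases of a br transcript of 8223 bases less the offset. Of the 2 protein-coding genes with a transcript of that length, br was the 1 not listed under its own identifier. Of 214 unmatched features with counts, 2 had the implied length of any br transcript.

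Library totals ran from 17627937 to 22940404 counts, so that a single count was worth between 0.0436 and 0.0567 CPM. Counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr on the 6 groups, and the quasi-likelihood F test in a fit of all 18 libraries with 1 mean per group, with Benjamini-Hochberg adjustment at 0.05 over the 9672 genes tested. The common biological coefficient of variation was 6%. Levels are CPM scaled by TMM, as mean ± SD with n = 3, and log2 fold changes are given ± SE. All adjusted p-values of single genes are from this edgeR fit. Where a group had no count of a gene, the fold is a lower bound against 3 counts summed over the group. Intervals of log2 fold changes come from the same fit and include the spread between libraries. Floors cover counting error only, since PCR copies were not marked. Principal components used log2 CPM (prior count 2) of the 2000 most variable genes.

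Genotypes were compared at each time, times within each genotype, and genotype effects between times through interaction contrasts. For restoration by br depletion, the genes called in E93RNAi against control with a log2 fold change of at least 1 either way were classed by their change from E93RNAi to E93RNAi+brRNAi: moved back, moved further, or not moved. Not moved means that this change did not pass the threshold. Both extremes were simulated 5 times from the fitted means and dispersions. Fixed lists of genes were tested with camera (limma 3.58.1, preset correlation), with Benjamini-Hochberg adjustment over the lists of a contrast, beside camera with an estimated correlation, and fry. The lists covered hormone cascade regulators, larval and pupal cuticle proteins, cuticle protein families, apical matrix proteins, chitin, pigmentation and sclerotization, planar polarity, hair actin, cell cycle, vein and intervein genes, wing patterning, extracellular matrix and integrins, cell death and JNK, autophagy, heat shock, immune genes, ribosomal proteins, the respiratory chain, and markers of muscle, hemocytes, neurons, sensory organs, glia, trachea and fat body. Several lists share genes, such as Col4a1 in the matrix and hemocyte lists.

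The groups, contrasts, lists, alternatives and the rule for named genes were set before the data were examined. The rule took Eip93F, br and rn, the 6 largest rises and falls per contrast among genes past the threshold with a symbol, at least 5 CPM in the higher group and no overlap between libraries, up to 3 members of each list by smallest adjusted p, 3 genes per direction in each interaction, and 4 genes per direction in each restoration class. Hormone cascade genes could be named in every contrast. The analysis was tested on simulated counts with 200 changed genes among 9672, for E93RNAi against control at 24 h. The changed genes were drawn only from those above a minimum level in control at 24 h, and all others were left unchanged. Of the genes changed by 1.25-fold 60% were recovered, with 94% at 1.5-fold, 98% at 2-fold and 98% at 4-fold, and 8 false calls among 183. Recovery of genes below that level was not tested. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, limma-trend on log2(cRPKM + 1) and log2(cRPKM + 0.1), other filters, thinned counts, fits of fewer groups, a replicate block and leaving out each replicate. List counts without E93RNAi 24 h replicate 3 and without E93RNAi+brRNAi 44 h replicate 3 were added after the data were seen.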

Results

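The data were gene-level read counts from 18 libraries of pupal wings, 3 for each of 6 groups: control, E93RNAi and E93RNAi+brRNAi at 24 h and 44 h after puparium formation. Library totals were between 17627937 and 22940404 counts, and 9672 genes were tested. E93, encoded by Eip93F, is a transcription factor of the ecdysone cascade that acts in adult development, and broad (br) encodes zinc finger factors of the pupal program. RNAi was driven by rn-Gal4, which follows rotund (rn) in the wing. By their labels, the groups address which transcripts change in wings with E93 RNAi and which of these changes are lost with br RNAi as well. No 2 libraries of a group had counts that agreed within sampling noise. The libraries do not show which cells held a transcript, which limits genes and lists best known from other tissues, such as muscle, neurons and fat body.

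The RNAi target Eip93F (FBgn0264490, chromosome 3R, 21949114 to 22014539) was not lower in the 24 h libraries labelled E93RNAi. Its level was 2077 ± 51.7 CPM in control and 2066 ± 193 CPM in the libraries labelled E93RNAi (SD, n = 3), a log2 fold change of -0.01 ± 0.06 with adjusted p = 0.935 and a 95% interval from -0.13 to 0.12. The single libraries were at 2018, 2115 and 2098 CPM in control and at 2043, 1886 and 2270 CPM in E93RNAi. At 44 h the means were 1285 ± 48.0 and 1156 ± 37.7 CPM (log2 fold change -0.15 ± 0.06, adjusted p = 0.0522), and this difference passed under 7 other settings. In the libraries labelled E93RNAi+brRNAi, Eip93F was at 2369 ± 40.8 CPM at 24 h (log2 fold change 0.19 against control, adjusted p = 0.0214) and at 867 ± 55.9 CPM at 44 h (log2 fold change -0.57, adjusted p = 1.53e-07). At 44 h the single libraries were at 1274, 1243 and 1337 CPM in control and at 1173, 1182 and 1113 CPM in E93RNAi. Those labelled E93RNAi+brRNAi were at 2359, 2414 and 2334 CPM at 24 h and at 922, 868 and 811 CPM at 44 h. The call at 24 h was lost without control replicate 1 (log2 fold change 0.17) and without E93RNAi+brRNAi replicate 2 (0.18). Because Eip93F transcript did not separate control from E93RNAi at 24 h, and was higher than control in E93RNAi+brRNAi, the groups are named below by their labels.

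The second target, br (FBgn0000210 in the deposited tables, chromosome X, 1575132 to 1664869), was higher in the libraries labelled E93RNAi. At 24 h it was at 14.78 ± 1.956 CPM in control and 95.1 ± 10.9 CPM in E93RNAi (log2 fold change 2.68 ± 0.13), and at 44 h at 1.70 ± 0.645 and 50.2 ± 2.57 CPM (4.86 ± 0.20). In the libraries labelled E93RNAi+brRNAi, br was at 17.96 ± 4.09 CPM at 24 h and 7.63 ± 1.18 CPM at 44 h, lower than in E93RNAi at both times (log2 fold change -2.40 ± 0.13 and -2.72 ± 0.15). Against control, br did not pass the threshold in E93RNAi+brRNAi at 24 h (0.28 ± 0.15, adjusted p = 0.159), except without E93RNAi+brRNAi replicate 3 (0.41), and was higher at 44 h (2.14 ± 0.26). The driver gene rn (FBgn0267337) was at 118 ± 3.05, 140 ± 10.7 and 115 ± 5.68 CPM in control, E93RNAi and E93RNAi+brRNAi at 24 h, and at 52.1 ± 2.02, 96.5 ± 0.698 and 71.0 ± 2.83 CPM at 44 h.

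**Figure D1:**
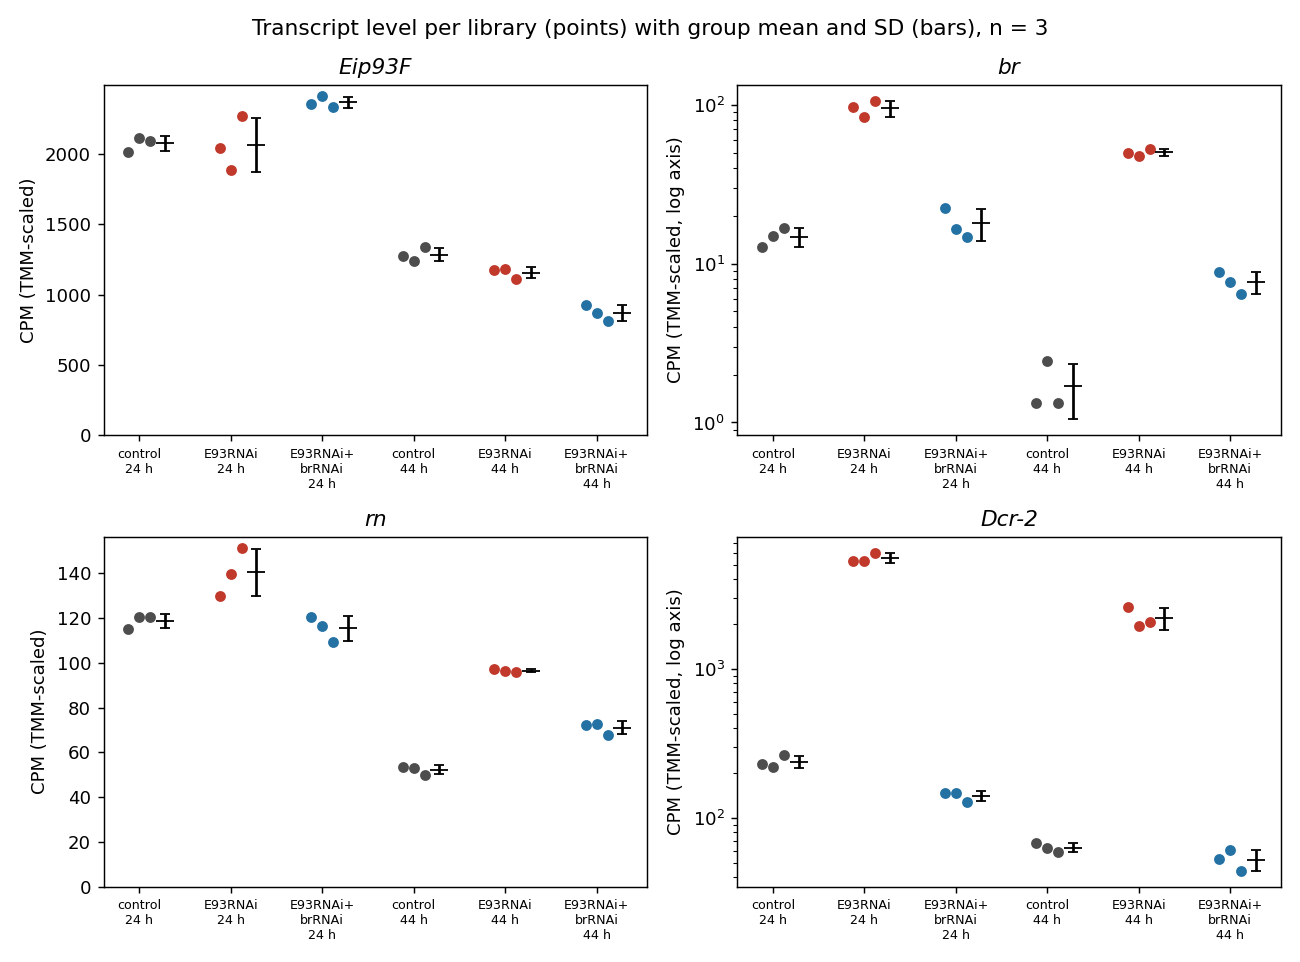
Level of Eip93F, br, rn and Dcr-2 in each library (points; CPM scaled by TMM, on a log axis for br and Dcr-2), with the mean and SD of each group of 3 libraries (bars). Eip93F in E93RNAi at 24 h lay between 1886 and 2270 CPM, around the control libraries, while br and Dcr-2 were higher in the E93RNAi libraries at both times.

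The first principal component, with 74.2% of the variance, separated the times, and the second, with 9.3%, separated the genotypes at 44 h. On the first component the 24 h libraries lay from -73.94 to -71.5 in control, from -63.76 to -62.03 in E93RNAi and from -52.14 to -46.52 in E93RNAi+brRNAi. The 44 h libraries lay from 56.32 to 58.13 in control, from 49.17 to 52.8 in E93RNAi and from 75.86 to 79.93 in E93RNAi+brRNAi. On the second component the 44 h libraries lay from -44.23 to -39.13 in control, from 1.08 to 2.92 in E93RNAi and from 31.81 to 35.23 in E93RNAi+brRNAi. The third component, with 7.1%, set E93RNAi apart at both times. At 24 h control lay from 18.59 to 23.69, E93RNAi from -19.14 to -18.65 and E93RNAi+brRNAi from 0.41 to 2.39. At 44 h these ranges were 8.03 to 8.68, -32.73 to -30.41 and 17.71 to 21.07.

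**Figure D2:**
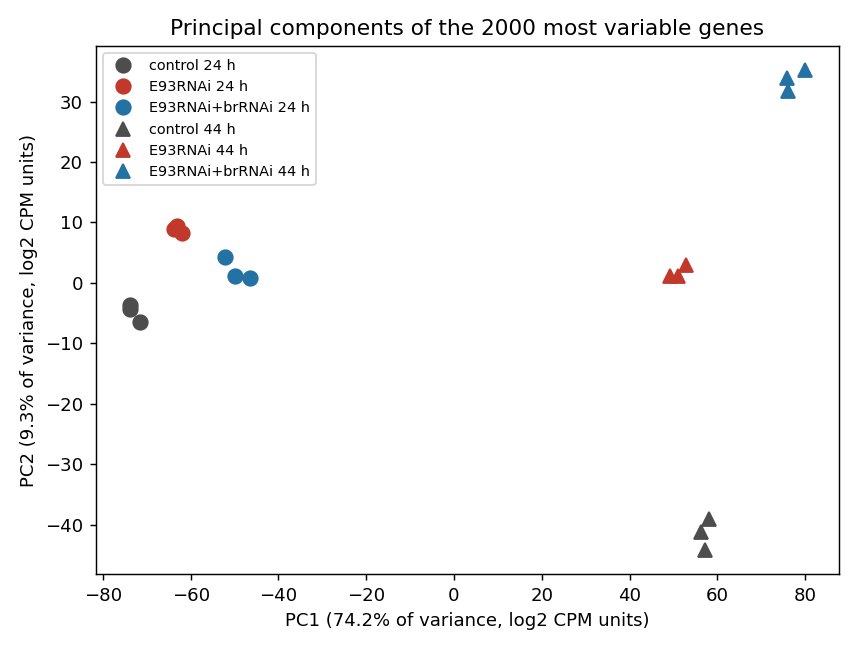
First and second principal components of log2 CPM for the 2000 most variable genes. Each point is a library, circles at 24 h and triangles at 44 h, coloured by genotype, and the 44 h control libraries lay below -39 and the E93RNAi+brRNAi libraries above 31 on the second component.

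At 24 h, the libraries labelled E93RNAi had more transcript of a muscle myosin, of Dicer-2 and of a cuticle protein, and little transcript of a pair of adjacent cytochrome P450 genes. Mhc, the muscle myosin heavy chain, was at 34.1 ± 2.08 CPM against 1.05 ± 0.737 in control (log2 fold change 5.03 ± 0.26). Dcr-2, the nuclease that makes small interfering RNAs (FBgn0034246, chromosome 2R, 17574979 to 17581525), was at 5549 ± 425 against 237 ± 22.1 CPM (4.55 ± 0.12). The protease gene stl was at 128 ± 6.78 against 7.76 ± 1.31 CPM. The cuticle protein gene Cpr50Ca was at 8.17 ± 1.30 against 0.498 ± 0.422 CPM. CG31798 (3.91 ± 0.24) and the neuropeptide-like Nplp4 (3.88 ± 0.26) completed the 6 largest rises. The P450 genes Cyp4p2 and Cyp4p1 lie next to each other on 2R, from 9237512 to 9242139. They were at 129 ± 4.27 and 55.7 ± 1.58 CPM in control and at 0.119 ± 0.0695 and 0.0908 ± 0.0806 CPM in E93RNAi. Further falls were in CG46025 (-6.68 ± 0.30), the metallothionein MtnA (-5.00 ± 0.26), spok, an enzyme gene of ecdysone synthesis best known from another tissue (-4.17 ± 0.32), and CG31313 (-4.02 ± 0.16).

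Of 24 hormone cascade genes tested, 10 rose, 1 fell and 13 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00241, adjusted p = 0.606 with an estimated correlation). Besides br, the nuclear receptor genes Hr4 (15.2 ± 0.480 to 40.3 ± 5.13 CPM) and Eip78C (39.3 ± 5.91 to 79.9 ± 5.60 CPM) rose. Ribosomal protein genes fell as a group: 54 of 81 fell and 1 rose, or 59 and 1 adjusted over the list alone (camera adjusted p = 6.70e-09, adjusted p = 0.606 with an estimated correlation). RpS13 had a log2 fold change of -0.33 ± 0.06. Likewise 38 of 67 respiratory chain genes fell and 4 rose, or 41 and 4 adjusted over the list alone (3.69e-06, adjusted p = 0.606 with an estimated correlation). E93RNAi 24 h replicate 3 had 7.92% of its counts in ribosomal protein genes, against 10.07% and 10.45% in the other libraries of its group. Without it, 31 ribosomal protein genes and 26 respiratory chain genes fell. Cell cycle genes fell by small amounts, 28 of 48 with 2 risen, or 32 and 3 adjusted over the list alone (camera adjusted p = 0.00214, adjusted p = 0.606 with an estimated correlation). Among them were the replication clamp gene PCNA (-0.69 ± 0.08) and the mitotic kinase gene aurB (-0.68 ± 0.07).

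Muscle genes went both ways, with 10 risen and 5 fallen of 23, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.0126, adjusted p = 0.364 with an estimated correlation). The giant sarcomere kinase gene bt was at 15.5 ± 2.19 against 3.96 ± 0.634 CPM and TpnC73F at 7.28 ± 0.452 against 0.749 ± 0.183 CPM. Among 16 sensory organ genes, 7 rose and 3 fell, or 8 and 3 adjusted over the list alone (0.0123, adjusted p = 0.364 with an estimated correlation). The gene of the sensory precursor factor sens went from 6.69 ± 1.49 to 29.9 ± 2.23 CPM. Immune genes fell, 9 of 16 with 7 not passing, or 10 adjusted over the list alone (0.00297, adjusted p = 0.150 with an estimated correlation). The antimicrobial peptide gene CecC fell from 5.09 ± 0.570 to 1.22 ± 0.232 CPM. In the fat body list 7 rose and 1 fell of 15, and as many adjusted over the list alone (0.0384, adjusted p = 0.606 with an estimated correlation). The storage protein gene Lsp1beta rose from 14.6 ± 1.03 to 54.6 ± 2.30 CPM, while Obp44a fell from 74.0 ± 24.1 to 4.62 ± 0.526 CPM. Of 28 vein and intervein genes 13 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.0397). Of 12 apical matrix genes 7 rose and 2 fell, or 8 and 2 adjusted over the list alone (0.0481). Both had adjusted p = 0.606 with an estimated correlation. Without E93RNAi 24 h replicate 3 both lists had camera adjusted p = 0.0756. In the matrix and integrin list, which did not pass as a group (9 rose and 5 fell of 27, adjusted p = 0.165), the laminin gene LanA rose from 86.3 ± 3.24 to 716 ± 72.3 CPM (3.05 ± 0.10). In all, 4249 genes passed, 2096 higher and 2153 lower, of which 835 had a log2 fold change of at least 1 either way (423 higher and 412 lower). Dcr-2 was among them, and effects of E93 RNAi cannot be told apart here from an unlabelled difference between the flies.

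The comparison of E93RNAi+brRNAi with control at 24 h addresses how wings with both RNAi transgenes differed from control. The nuclear receptor gene Hr3, part of the ecdysone response, was at 61.9 ± 21.2 CPM against 1.45 ± 0.345 in control (log2 fold change 5.42 ± 0.25). The pigment gene y was at 7.27 ± 1.03 against 0.222 ± 0.208 CPM (5.04 ± 0.42). C901 (5.60 ± 0.45), Nplp4 (4.93 ± 0.24), CG6431 (4.08 ± 0.30) and the cuticle protein gene Cpr56F (3.93 ± 0.40) also rose. The largest falls by the naming rule were in spok (12.2 ± 4.44 to 0.198 ± 0.158 CPM), wry (-5.39 ± 0.36) and the acetylcholine receptor subunit gene nAChRalpha7 (9.72 ± 2.49 to 0.523 ± 0.175 CPM). CG43737 (-4.20 ± 0.30), Obp44a (74.0 ± 24.1 to 4.14 ± 0.341 CPM) and CG4757 (58.6 ± 12.9 to 3.63 ± 0.875 CPM) followed. Transcripts of spok, nAChRalpha7 and Obp44a are best known from other tissues, and it cannot be read from these libraries whether those in control came from wing cells.

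Cell cycle genes fell almost throughout: 42 of 48 fell and 2 rose, and as many adjusted over the list alone (camera adjusted p = 7.29e-15, adjusted p = 0.151 with an estimated correlation). The replication helicase gene Mcm7 was at 67.9 ± 5.89 against 116 ± 2.71 CPM, and the cytokinesis gene feo at 71.7 ± 4.30 against 118 ± 0.407 CPM. Apical matrix genes rose, 9 of 12, or 10 with 1 fallen adjusted over the list alone (2.33e-08, adjusted p = 0.151 with an estimated correlation). The zona pellucida domain genes mey (111 ± 7.97 to 489 ± 47.6 CPM) and m (15.4 ± 4.74 to 163 ± 26.6 CPM) were among them. Of 20 hair actin genes 9 rose and 11 did not pass, or 11 rose adjusted over the list alone (0.000118, adjusted p = 0.413 with an estimated correlation). They included sha (2.06 ± 0.10) and the forked gene f (1.46 ± 0.09), which act in wing hairs and bristles. In the pigmentation and sclerotization list 6 rose and 2 fell of 19, or 7 and 2 adjusted over the list alone (0.00843, adjusted p = 0.151 with an estimated correlation). The ebony gene e rose from 2.25 ± 0.156 to 23.9 ± 5.27 CPM. Neuron markers fell, 8 of 18, or 9 adjusted over the list alone (0.00286, adjusted p = 0.515 with an estimated correlation), such as cpx (12.8 ± 3.61 to 6.34 ± 0.766 CPM), and whether their transcripts in control came from the wing is open as well. Hormone cascade genes had 8 risen and 3 fallen of 24, or 9 and 3 adjusted over the list alone (0.0157, adjusted p = 0.515 with an estimated correlation). Matrix and integrin genes had 10 and 3 of 27, or 10 and 5 adjusted over the list alone (0.0444, adjusted p = 0.560 with an estimated correlation). In all, 2952 genes passed, 1420 higher and 1532 lower, and 673 of them had a log2 fold change of at least 1 either way (331 higher and 342 lower).

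E93RNAi+brRNAi against E93RNAi at 24 h compares groups whose labels differ by the br transgene and which also differed in Dcr-2. Cyp4p2 and Cyp4p1 were higher in E93RNAi+brRNAi, at 79.8 ± 7.06 and 38.9 ± 3.15 CPM, and CG46025 at 5.41 ± 0.738 CPM. C901 (4.88 ± 0.40), Cyp4g1, a P450 gene of hydrocarbon synthesis (4.65 ± 0.42), and the antimicrobial peptide gene Dro (4.22 ± 0.25) were also higher. Mhc fell to 0.742 ± 0.142 CPM and Dcr-2 to 141 ± 10.7 CPM. Gcat (-3.41 ± 0.25), the tropomyosin gene Tm2 (-3.20 ± 0.25), the myosin light chain gene Mlc1 (-3.18 ± 0.25) and krimp (-2.97 ± 0.25) fell too.

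Ribosomal protein genes rose, 52 of 81 with 1 fallen, or 60 and 1 adjusted over the list alone (camera adjusted p = 1.30e-09, adjusted p = 0.649 with an estimated correlation). Likewise 49 of 67 respiratory chain genes rose with 1 fallen, or 54 and 1 adjusted over the list alone (2.01e-09, adjusted p = 0.641 with an estimated correlation). Without E93RNAi 24 h replicate 3, which had the lower ribosomal protein share, 34 ribosomal protein genes and 34 respiratory chain genes rose. Apical matrix genes rose, 9 of 12, or 9 with 1 fallen adjusted over the list alone (5.75e-06, adjusted p = 0.164 with an estimated correlation). Immune genes rose, 8 of 16 with 1 fallen, or 11 and 1 adjusted over the list alone (0.000468, adjusted p = 0.0697 with an estimated correlation). Hair actin genes had 9 risen and 3 fallen of 20, and as many adjusted over the list alone (0.0288, adjusted p = 0.649 with an estimated correlation), or 9 and 1 without that library. Cell cycle genes fell, 32 of 48 with 2 risen, or 34 and 2 adjusted over the list alone (2.22e-05, adjusted p = 0.545 with an estimated correlation). Muscle genes fell, 12 of 23 with 1 risen, and as many adjusted over the list alone (2.22e-05, adjusted p = 0.0791 with an estimated correlation). So did 9 of 16 sensory organ genes with 2 risen, again as many adjusted over the list alone (0.0142, adjusted p = 0.303 with an estimated correlation). In this list sens fell to 5.97 ± 0.346 CPM. LanA fell to 145 ± 11.5 CPM (-2.30 ± 0.09). In all, 3989 genes passed, 1952 higher and 2037 lower, and 576 had a log2 fold change of at least 1 either way (298 higher and 278 lower).

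At 44 h, the libraries labelled E93RNAi held more transcript of cuticle proteins and sensory organ genes than control. CG9452 had no count in the control libraries and 6.09 ± 0.277 CPM in E93RNAi, at least 114-fold higher than the floor of 0.0533 CPM. CG6912 was at 65.2 ± 2.40 against 0.593 ± 0.285 CPM. CG42331 was at 364 ± 55.1 against 5.86 ± 1.75 CPM and CG5639 at 209 ± 24.9 against 5.46 ± 1.67 CPM. CG15282 (6.04 ± 0.40) and CG42323 (5.29 ± 0.29) rose as well. Cyp4p2 and Cyp4p1 were low again (97.0 ± 8.37 to 0.379 ± 0.126 and 38.4 ± 0.276 to 0.305 ± 0.135 CPM). The adipokinetic hormone gene Akh, best known from another tissue (-4.78 ± 0.47), CG14075 (-4.76 ± 0.50), the flight muscle actin gene Act88F (57.9 ± 8.60 to 2.82 ± 0.364 CPM) and CG33655 (-4.14 ± 0.30) fell. Dcr-2 was at 2202 ± 366 against 63.0 ± 4.51 CPM (5.13 ± 0.13), so the limit given for this comparison at 24 h holds at 44 h as well.

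Of 60 genes of the cuticle protein families 34 rose and 6 fell, and as many adjusted over the list alone (camera adjusted p = 1.12e-07, adjusted p = 0.0125 with an estimated correlation). TwdlE rose from 25.5 ± 2.37 to 224 ± 4.25 CPM and Cpr97Ea from 101 ± 1.32 to 284 ± 8.93 CPM. Larval and pupal cuticle genes rose, 5 of 9, and as many adjusted over the list alone (0.0122, adjusted p = 0.0989 with an estimated correlation). Edg78E went from 0.477 ± 0.0839 to 3.65 ± 0.620 CPM. The same list had run the other way in E93RNAi at 24 h, with 0 risen and 5 fallen. It had not passed there (camera adjusted p = 0.0725, adjusted p = 0.364 with an estimated correlation). Only 9 of its 27 members matched in the data were tested. Sensory organ genes rose, 13 of 16, or 14 with 1 fallen adjusted over the list alone (7.20e-07, adjusted p = 0.0189 with an estimated correlation). The transcription factor genes pros (38.6 ± 0.841 to 67.4 ± 2.98 CPM) and ham (6.25 ± 0.362 to 12.9 ± 0.141 CPM) were examples. Cell cycle genes were higher, 31 of 48 with 3 fallen, or 33 and 3 adjusted over the list alone (1.14e-08, adjusted p = 0.167 with an estimated correlation). Klp61F rose from 2.50 ± 0.199 to 9.28 ± 0.436 CPM, while dpa fell from 52.0 ± 2.18 to 23.3 ± 1.36 CPM. Heat shock genes rose, 8 of 13, or 8 with 1 fallen adjusted over the list alone (0.0113, adjusted p = 0.167 with an estimated correlation). Hsp23 rose from 349 ± 23.5 to 1006 ± 47.5 CPM.

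Other groups fell at 44 h. Apical matrix genes fell, 9 of 12 with 1 risen, and as many adjusted over the list alone (camera adjusted p = 0.000380, adjusted p = 0.167 with an estimated correlation). In this list neo went from 7127 ± 144 to 3514 ± 81.5 CPM. Matrix and integrin genes fell, 17 of 27 with 4 risen, or 17 and 5 adjusted over the list alone (0.000347, adjusted p = 0.207 with an estimated correlation). SPARC fell from 268 ± 8.27 to 123 ± 5.93 CPM, whereas LanA rose from 145 ± 8.95 to 396 ± 23.1 CPM. Muscle genes fell, 14 of 23 with 5 risen, and as many adjusted over the list alone (0.00518, adjusted p = 0.167 with an estimated correlation). In all, 3826 genes passed, 1996 higher and 1830 lower, and 1151 had a log2 fold change of at least 1 either way (700 higher and 451 lower). With scaling by total count only, 4511 passed, 3263 higher and 1248 lower, since the median log2 fold change of all genes was then 0.12.

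E93RNAi+brRNAi at 44 h was marked by transcripts that had no count in control wings. CG13947 was at 179 ± 50.8 CPM, at least 3360-fold above the control floor of 0.0533 CPM, and CG43680 at 85.1 ± 18.6 CPM, at least 1600-fold above it. For CG13159, CG43679, CG32198 and CG8708 the level was at least 1210-fold, 1110-fold, 993-fold and 912-fold higher than that floor. The eye pigment genes cn (5.49 ± 1.75 to 0.212 ± 0.112 CPM) and st (9.27 ± 3.91 to 0.666 ± 0.236 CPM) fell. So did the neuropeptide gene sNPF (12.6 ± 5.73 to 0.851 ± 0.268 CPM), Rgk2 (-4.40 ± 0.39), CG5653 (-4.13 ± 0.39) and CG34377 (-3.95 ± 0.24). The genes cn, st and sNPF are best known from other tissues, and these libraries do not show whether their transcripts in control came from wing cells. Dcr-2 was at 52.4 ± 8.32 against 63.0 ± 4.51 CPM (-0.27 ± 0.12, adjusted p = 0.0705).

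Of the cuticle protein families 36 of 60 rose and 6 fell, or 37 and 6 adjusted over the list alone (camera adjusted p = 2.06e-08, adjusted p = 0.00724 with an estimated correlation). Cpr76Bc rose from 51.5 ± 1.81 to 1803 ± 387 CPM and Cpr66D from 7.80 ± 0.859 to 211 ± 64.8 CPM. Chitin genes rose, 15 of 25 with 3 fallen, or 15 and 4 adjusted over the list alone (3.01e-05, adjusted p = 0.205 with an estimated correlation). They included the chitinase gene Cht7 (82.6 ± 13.0 to 1120 ± 101 CPM) and knk, which protects chitin (44.7 ± 2.49 to 159 ± 13.5 CPM). In the pigmentation and sclerotization list 11 rose and 3 fell of 19, and as many adjusted over the list alone (0.0237, adjusted p = 0.224 with an estimated correlation). The pigment gene y was at 63.74 ± 13.95 against 0.707 ± 0.0941 CPM. Wing patterning genes fell, 21 of 34 with 5 risen, and as many adjusted over the list alone (0.00111, adjusted p = 0.515 with an estimated correlation). The transcription factor gene nub fell from 579 ± 23.1 to 367 ± 26.8 CPM. Vein and intervein genes fell, 12 of 28 with 3 risen, or 14 and 3 adjusted over the list alone (0.0391, adjusted p = 0.515 with an estimated correlation). Among them sog fell from 296 ± 5.16 to 173 ± 11.3 CPM. Without E93RNAi+brRNAi 44 h replicate 3 this list had camera adjusted p = 0.05. Without that library the cell cycle list passed (20 rose and 5 fell of 48, adjusted p = 0.00706), against 16 and 7 with it (0.0905). The hormone cascade list did not pass (9 rose and 12 fell of 24, adjusted p = 0.879, median log2 fold change -0.11 and mean 0.35), but EcR, the ecdysone receptor gene (111 ± 5.89 to 265 ± 20.6 CPM), and Eip74EF (119 ± 2.72 to 309 ± 41.6 CPM) rose. In all, 4406 genes passed, 2224 higher and 2182 lower, and 1018 had a log2 fold change of at least 1 either way (766 higher and 252 lower). By total count only, 4838 passed, 1881 higher and 2957 lower.

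Against E93RNAi at 44 h, chitin genes were higher and sensory organ genes lower in E93RNAi+brRNAi. CG43680 and CG43679 had no count in E93RNAi and were at least 1610-fold and 1120-fold above its floor of 0.0528 CPM in E93RNAi+brRNAi. CG13947 had 2 counts in E93RNAi and 9238 in E93RNAi+brRNAi. CG12310, CG13946 and the prolyl hydroxylase gene PH4alphaSG2 were at least 206-fold, 189-fold and 176-fold above that floor. CG7203 (-5.51 ± 0.42), Dcr-2 (-5.39 ± 0.13), the taste receptor gene Gr64a (6.27 ± 0.618 to 0.210 ± 0.128 CPM), Nplp3 (-4.48 ± 0.28), Culd (93.8 ± 1.14 to 9.97 ± 0.378 CPM) and CG11382 (-2.96 ± 0.33) fell.

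Chitin genes rose, 21 of 25 with 2 fallen, and as many adjusted over the list alone (camera adjusted p = 2.38e-08, adjusted p = 0.0440 with an estimated correlation). The chitin-binding gene Gasp rose from 329 ± 8.59 to 1261 ± 175 CPM and exp from 28.1 ± 2.52 to 139 ± 7.59 CPM. Sensory organ genes fell, 12 of 16, and as many adjusted over the list alone (3.26e-06, adjusted p = 0.0440 with an estimated correlation). The proneural gene sc fell from 8.41 ± 0.339 to 2.81 ± 0.139 CPM. Muscle genes rose, 16 of 23 with 2 fallen, or 17 and 2 adjusted over the list alone (0.000226, adjusted p = 0.106 with an estimated correlation). Act88F was at 52.2 ± 14.96 against 2.82 ± 0.364 CPM. Matrix and integrin genes rose, 16 of 27 with 4 fallen, the same adjusted over the list alone (0.0162, adjusted p = 0.486 with an estimated correlation). In that list LanA fell to 119 ± 17.9 CPM. Immune genes rose, 6 of 16, also adjusted over the list alone (0.0184, adjusted p = 0.128 with an estimated correlation). In addition 11 of 19 pigmentation and sclerotization genes rose with 4 fallen, or 11 and 5 adjusted over the list alone (0.0236, adjusted p = 0.170 with an estimated correlation). Cell cycle genes fell, 27 of 48 with 4 risen, or 29 and 4 adjusted over the list alone (0.000161, adjusted p = 0.452 with an estimated correlation). Wing patterning genes fell, 21 of 34 with 1 risen, the same adjusted over the list alone (1.37e-05, adjusted p = 0.372 with an estimated correlation). Heat shock genes fell, 8 of 13 with 3 risen, the same adjusted over the list alone (0.0111, adjusted p = 0.166 with an estimated correlation). Vein and intervein genes fell, 12 of 28 with 5 risen, the same adjusted over the list alone (0.0255, adjusted p = 0.488 with an estimated correlation). The hair actin list passed without E93RNAi+brRNAi 44 h replicate 3 (12 rose and 3 fell of 20, adjusted p = 0.0186) and not with it (10 and 4, 0.0541). In all, 4717 genes passed, 2408 higher and 2309 lower, and 1047 had a log2 fold change of at least 1 either way (691 higher and 356 lower). By total count only, 5922 passed, 1516 higher and 4406 lower, with a median log2 fold change of all genes of -0.20.

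**Figure D3:**
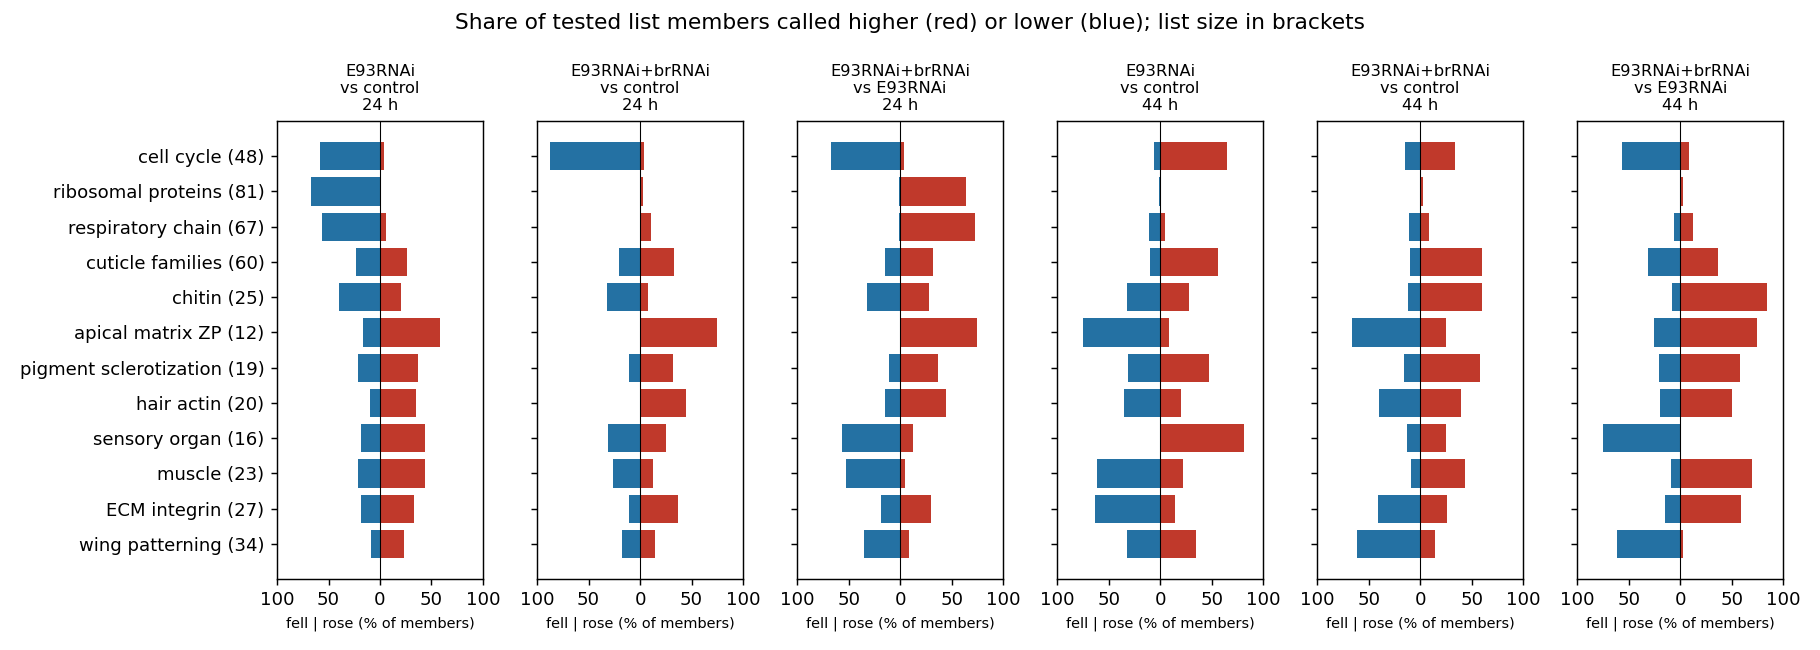
Share of the tested members of 12 gene lists that were called higher (red, right) or lower (blue, left) in each of the 6 genotype comparisons, in percent of members, with list size in brackets. Cuticle protein families rose against control at 44 h in both RNAi genotypes (34 and 36 of 60), and chitin genes rose from E93RNAi to E93RNAi+brRNAi at 44 h (21 of 25).

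The comparison of times in control wings addresses what changed during normal development, and it called more genes (7280) than any genotype comparison (at most 4717). CG15888 rose from 0.136 ± 0.151 to 1245 ± 152 CPM and C901 from 0.114 ± 0.0692 to 722 ± 15.4 CPM. The Osiris family genes Osi3 and Osi22, expressed in cuticle-secreting epithelia, rose from 2.35 ± 0.528 and 4.08 ± 1.58 to 4878 ± 417 and 6677 ± 442 CPM. Osi8 (11.44 ± 0.22) and Osi11 (11.18 ± 0.21) rose with them. The 6 largest falls by the naming rule included CG1850 (8948 ± 631 to 29.9 ± 3.58 CPM), CG9747 (1552 ± 74.0 to 5.67 ± 0.375 CPM), CG15212 (-8.53 ± 0.27) and Cks30A, a cell cycle kinase subunit gene (55.9 ± 1.55 to 0.264 ± 0.0927 CPM). The others were Brd and msd1, which went from 604 and 834 counts to 1 and 3. Cell cycle genes fell, 46 of 48 with 2 risen (camera adjusted p = 7.02e-18, adjusted p = 0.142 with an estimated correlation). All 12 apical matrix genes rose (4.38e-07, adjusted p = 0.142 with an estimated correlation), and neo went from 504 ± 7.04 to 7127 ± 144 CPM. Matrix and integrin genes rose, 21 of 27 with 3 fallen (4.46e-05, adjusted p = 0.257 with an estimated correlation). Wing patterning genes fell, 25 of 34 with 3 risen (0.000245, adjusted p = 0.399 with an estimated correlation). The counts of these lists were the same adjusted over the list alone. Hair actin genes (11 rose and 4 fell of 20, adjusted p = 0.0235), pigmentation and sclerotization genes (13 and 4 of 19, 0.0329), hemocyte markers (12 and 2 of 16, 0.0329) and sensory organ genes (4 and 12 of 16, 0.0430) passed camera. In the same order they had adjusted p = 0.443, 0.257, 0.257 and 0.303 with an estimated correlation. Adjusted over the list alone, hemocyte markers had 12 risen and 3 fallen, and hair actin, pigmentation and sensory organ genes the same counts. Hr3 rose from 1.45 ± 0.345 to 2204 ± 121 CPM.

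The time change passed for 7280 genes in control (3591 higher and 3689 lower), 7205 in E93RNAi (3681 and 3524) and 7331 in E93RNAi+brRNAi (3656 and 3675). By total count only there were 7546 in control (2819 and 4727) and 7763 in E93RNAi+brRNAi (2779 and 4984), with median log2 fold changes of all genes of -0.22 and -0.27, and of -0.10 in E93RNAi. The interaction contrasts, which test whether a genotype effect differs between times, passed for 3663 genes for E93RNAi against control (1920 higher and 1743 lower), 3726 for E93RNAi+brRNAi against control (1934 and 1792) and 3240 for E93RNAi+brRNAi against E93RNAi (1690 and 1550). By total count only the first gave 3847 (2581 and 1266) and the last 4179 (1157 and 3022), with medians of 0.11 and -0.18, and upper quartile scaling gave 3499 for the last (1454 and 2045). In E93RNAi against control 2007 genes were called at both times, against 1680.8 for independent lists. Of these, 686 had opposite signs at 24 h and 44 h. All 686 passed the interaction contrast, which their selection by opposite calls makes nearly certain. A genotype effect that reversed with time was found for 792 of 1626 such genes in E93RNAi+brRNAi against control and for 543 of 2290 in E93RNAi+brRNAi against E93RNAi, where independent lists would have shared 1344.8 and 1945.4.

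The comparison of all 3 genotypes addresses which changes were smaller in the libraries labelled with the br transgene as well. It was made on the genes called in E93RNAi against control with a log2 fold change of at least 1 either way. At 24 h, 379 of 835 (45.4%) moved back towards control in E93RNAi+brRNAi, and 234 (28% of the 835) moved back and were no longer called against control. A further 404 (48.4%) did not move and 52 (6.2%) moved further away. At 44 h, 665 of 1151 (57.8%) moved back, and 324 (28.1% of the 1151) moved back and were no longer called. There 342 (29.7%) did not move and 144 (12.5%) moved further. Genes classed as not moved include those whose change from E93RNAi was too uncertain to pass. An example at 44 h is cn, with a log2 fold change of -1.08 from E93RNAi (adjusted p = 0.213). The median remaining effect was 59.6% at 24 h and 54.5% at 44 h. At 44 h br itself kept 44% of its log2 effect and was still called against control. It was at 1.70, 50.2 and 7.63 CPM in control, E93RNAi and E93RNAi+brRNAi. Genes that kept an effect there therefore cannot be taken as independent of br. Simulation without an effect of br depletion gave 97.7% and 98.4% remaining with 0% moved back, and simulation of complete return gave 2.6% and 1.7% remaining with 92.5% and 92.7% moved back. At 24 h, 60.3% of the raised genes moved back and 30.1% of the lowered genes, and at 44 h 55.3% and 61.6%. Both contrasts share the E93RNAi libraries. Dcr-2 differed between these groups as well (5549 and 141 CPM at 24 h) and no library had the br transgene alone, so the return cannot be assigned to br. Whether E93 was depleted equally in both groups cannot be read from Eip93F transcript. At 24 h this transcript was not lower than control in either group, and at 44 h it was lowest in E93RNAi+brRNAi. Independent lists of these sizes would have shared 89.1 raised and 83.1 lowered genes at 24 h, against 255 and 124 observed, and 167.1 and 112.3 at 44 h, against 387 and 278.

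Named members show the range of these responses. Mhc, Tm2 and Gcat (5.03, 3.42 and 3.57 in E93RNAi against control at 24 h) had log2 fold changes of -0.49, 0.22 and 0.16 in E93RNAi+brRNAi against control. Cyp4p2 kept 6.9% of its effect at 24 h and 6.1% at 44 h, and Act88F 3.4% at 44 h. Cyp4p3, outside the naming rule and low throughout, had 0 CPM in every E93RNAi library at 24 h. It was at 1.807 to 2.017 CPM in control and 0.8527 to 1.607 CPM in E93RNAi+brRNAi there. Whether RNAi or another difference between the flies lowered the Cyp4p genes cannot be told from this design. stl kept 56.1% at 24 h and Cpr50Ca 86.6%. Hr3 moved further at 24 h (6.24 CPM in E93RNAi and 61.9 in E93RNAi+brRNAi), as did the transcription factor gene fru (5.41 ± 1.57 CPM in control, 22.0 in E93RNAi and 52.2 in E93RNAi+brRNAi), and so did CG42331 (364 and 3608 CPM) and the protease gene sona (7.25 and 33.8 CPM) at 44 h. CG14636 did not move at 44 h (172 and 168 CPM). Several genes that did not move were higher in control with a wide spread: Obp44a (74.0 ± 24.1 CPM in control, 4.62 and 4.14 in the RNAi groups at 24 h) and abd-A, a Hox gene of the abdomen (7.18 ± 1.40, 0.614 and 0.557). At 44 h this held for sNPF (12.6 ± 5.73, 1.08 and 0.851), cn (5.49 ± 1.75, 0.456 and 0.212) and, moving further, ninaC, a photoreceptor myosin gene (8.20 ± 1.73, 2.54 and 1.13). These genes are best known from other tissues, and whether their transcripts in control came from wing cells cannot be read from these libraries.

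Across all 9672 genes, which are not independent replicates, the effects of E93RNAi and of E93RNAi+brRNAi against the same control had a correlation of 0.62 at 24 h and 0.53 at 44 h, against 0.52 and 0.48 in simulation without any effect. Their covariance was 0.249 and 0.349, against 0.017 and 0.016 in simulation. The simulation also shared the controls, so their spread between libraries is in the 0.017 and 0.016. With 3 control libraries the controls could not be split into groups of at least 2. A deviation common to all control libraries is not in the simulation and may give part of the excess. Restoration counts over genes with a mean of at least 5 CPM were 134 of 224 (59.8%) at 24 h and 279 of 451 (61.9%) at 44 h. Most of the 835 and 1151 genes thus lay below that mean, and the shares moved back over all of them were lower (45.4% and 57.8%).

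**Figure D4:**
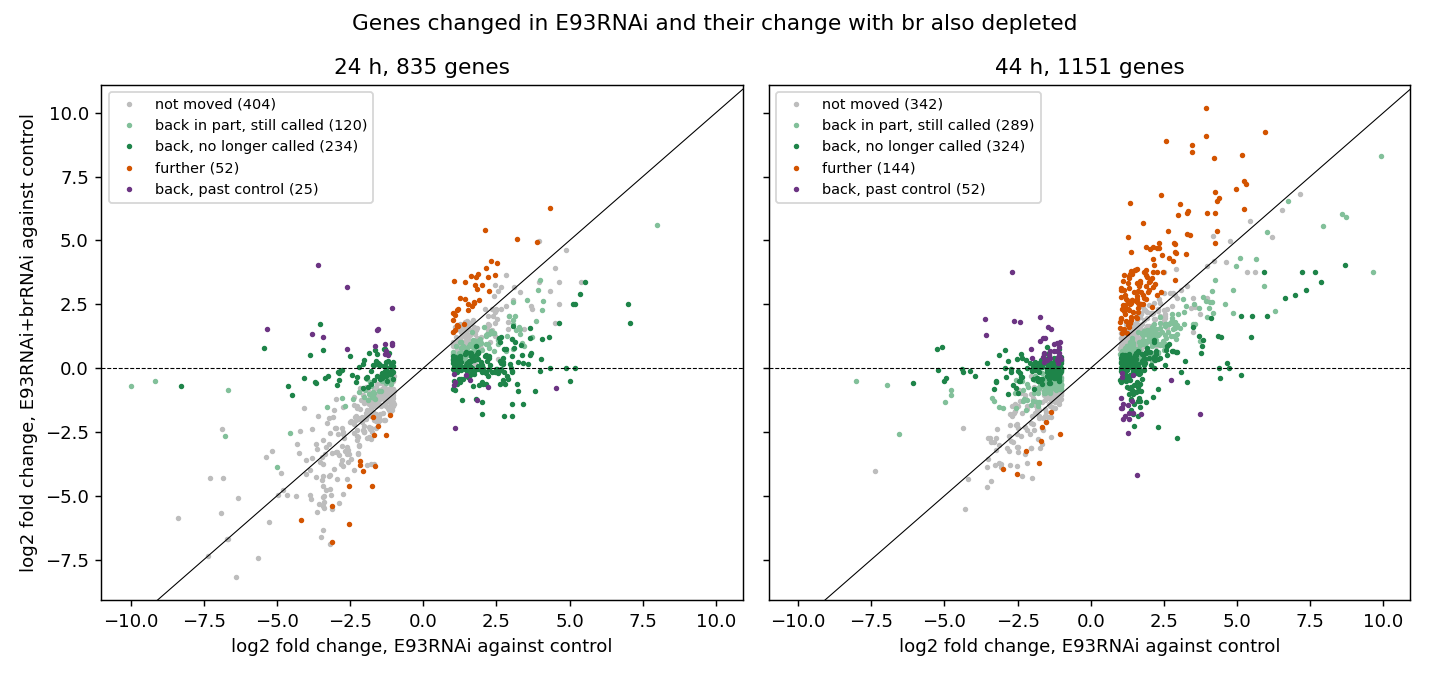
Log2 fold change in E93RNAi+brRNAi against control plotted over that in E93RNAi against control, for the 835 genes at 24 h and 1151 genes at 44 h changed in E93RNAi. Each point is a gene, coloured by its class, with genes moved back (379 and 665) shifted from the solid line of equal effect towards the dashed line of no difference from control, 25 and 52 of them still called against control on its other side, and fitted values of genes with no count in a group depend on the prior count.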

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

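The regroupings reported in this part were chosen before their results were seen.

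Each result here is a genotype effect that differed between 24 h and 44 h by a test of the difference itself, the interaction contrast of the edgeR fit. The contrast passed for 3663 genes in E93RNAi against control, 3726 in E93RNAi+brRNAi against control and 3240 in E93RNAi+brRNAi against E93RNAi. In each contrast the 3 genes with the smallest adjusted p per direction are given, as log2 difference of the time changes with mean CPM.

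For E93RNAi against control, the calponin-family gene Chd64 had a log2 interaction of 2.45 ± 0.07, going from 69.3 to 51.3 CPM in control and from 74.3 to 302 CPM in E93RNAi. The cuticle protein gene Cpr12A had 3.64 ± 0.12, with 387 to 7.56 CPM in control and 400.4 to 98.0 in E93RNAi. The JAK-STAT responsive vir-1 had 2.10 ± 0.07, with 204 to 37.0 and 244 to 189 CPM. In the other direction, uncNacbeta had -2.87 ± 0.11 (45.9 to 72.0 and 161 to 34.5 CPM), the tubulin gene alphaTub85E -4.16 ± 0.16 (6.6 to 42.3 and 33.62 to 12.03 CPM) and MESR3 -1.81 ± 0.07 (16.2 to 204 and 40.9 to 147 CPM).

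For E93RNAi+brRNAi against control, Rsod had 3.60 ± 0.10 (53.0 to 5.48 CPM in control and 43.8 to 55.0 in E93RNAi+brRNAi), CG3036 4.26 ± 0.12 (1097 to 21.8 and 539 to 206 CPM) and CG3777 3.74 ± 0.13 (262 to 28.2 and 171 to 246 CPM). RluA-1 had -3.61 ± 0.11 (7.31 to 870.2 and 56.1 to 546 CPM), cysu -3.12 ± 0.10 (23.9 to 995 and 116 to 556 CPM) and CG4914 -2.66 ± 0.09 (31.8 to 1387 and 131 to 899 CPM).

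For E93RNAi+brRNAi against E93RNAi, nahoda had 2.38 ± 0.08 (154 to 92.1 CPM in E93RNAi and 123 to 383 in E93RNAi+brRNAi), CG14257 4.25 ± 0.17 (66.4 to 36.4 and 21.9 to 228 CPM) and exp, named expansion for its part in tracheal tube growth, 3.35 ± 0.13 (32.9 to 28.1 and 15.9 to 139 CPM). The Vajk family gene Vajk3 had -4.45 ± 0.18 (1.75 to 14.8 and 18.7 to 7.24 CPM), Culd -3.86 ± 0.17 (12.6 to 93.8 and 19.4 to 9.97 CPM) and js -1.69 ± 0.08 (45.6 to 95.9 and 74.0 to 48.2 CPM).

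Regrouping the libraries within each time compared these counts with those of groups of mixed genotype. Of 100 regroupings drawn, 1, the real one, gave as many genes in each of the 3 interaction contrasts. The real counts were 3663, 3726 and 3240, and the highest of the other regroupings gave 1958, 2199 and 2427. Mixed groups carry the genotype differences at each time as spread, which lowers their calls whatever the interaction. The regroupings therefore cannot exclude chance for the interaction itself. For the comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many genes. The real counts were 4249, 2952 and 3989 at 24 h, 3826, 4406 and 4717 at 44 h, and 7280, 7205 and 7331 for the time changes. The highest other split gave 0 calls in each by edgeR. At an unadjusted p under 0.05 the other splits gave at most 955, 466 and 875 genes at 24 h, 592, 922 and 758 at 44 h, and 254, 554 and 498 for the time changes. The 20 splits of the E93RNAi and E93RNAi+brRNAi libraries are likewise too few for restoration, with 379 and 665 genes moved back in the real split and at most 264 and 601 in another. Those 264 and 601 are the counts with the labels of both groups fully exchanged, which keeps the real groups apart. The median of the other splits was 0 at both times.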

How the results depend on the processing

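The list counts without single libraries were chosen after the data were seen, and all other alternatives before. Counts of called genes in the 12 comparisons stayed within 1.5 times under every other setting except the fold change minimum. With a log2 fold change of at least 1 either way the counts were 835, 673, 576, 1151, 1018 and 1047 for the genotype comparisons in the order reported, 2994, 2666 and 2946 for the time changes, and 1015, 1221 and 791 for the interactions. Leaving out 1 replicate gave 3380 to 4185, 2385 to 2664 and 3064 to 3939 at 24 h, 3333 to 3522, 3769 to 4166 and 4074 to 4487 at 44 h, 6947 to 7027, 6862 to 7006 and 7041 to 7153 for the time changes, 3185 to 3783, 3264 to 3686 and 2802 to 3267 for the interactions, and 322 to 375 and 616 to 666 for restoration. Restoration gave 2236 of 4249 (52.6%) and 2056 of 3826 (53.7%) with no minimum fold change. It gave 169 of 237 (71.3%) and 340 of 511 (66.5%) by limma-trend on log2(cRPKM + 1), and 134 of 224 (59.8%) and 279 of 451 (61.9%) at a mean of at least 5 CPM. All of these start from other sets of genes. Of 56 list calls by camera, 5 held with an estimated correlation: cuticle protein families and sensory organs in E93RNAi against control at 44 h, cuticle protein families in E93RNAi+brRNAi against control, and chitin and sensory organs in E93RNAi+brRNAi against E93RNAi. By fry, which does not compare a list with other genes, 123 passed.

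Same-numbered replicates did not deviate together: over 45 pairs the correlation of deviations ran from -0.183 to 0.088 with a median of -0.02, so no pairing by number was visible. Whether same-numbered libraries were collected or prepared together is not in the labels. With a replicate block the counts were 4082, 2824, 3822, 3689, 4278 and 4587 for the genotype comparisons, 7191, 7144 and 7274 for the time changes, 3521, 3580 and 3071 for the interactions, 369 and 659 for restoration and 55 list calls.

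The difference of Eip93F between E93RNAi and control at 24 h, not called in any setting, changed sign: 0.00 with DESeq2 size factors and with the DESeq2 test, 0.02 by total count and without a filter, 0.01 in both limma-trend fits, 0.01 without control replicate 2, and 0.00 and 0.05 without E93RNAi replicates 1 and 2. Leaving out 1 replicate gave -0.08 to 0.05. At 44 h it passed at -0.15 or -0.16 under 7 settings. The br interaction of E93RNAi+brRNAi against E93RNAi was 0.07 by limma-trend on log2(cRPKM + 1), and that of Dcr-2 0.05 without E93RNAi 44 h replicate 1 and 0.04 without E93RNAi+brRNAi 44 h replicate 3 (-0.18 to 0.05 over all replicates left out). Neither was called in the analysis reported, and the cause was not tested. Over the other single-gene results and the ribosomal and respiratory list counts in their larger direction, 11621 values under the alternatives kept direction and call or size, 99 lost the call and 19 gained it. The other 5 were list counts. Ribosomal genes fallen in E93RNAi at 24 h went from 54 to 31, and those risen from there to E93RNAi+brRNAi from 52 to 34, without E93RNAi 24 h replicate 3. Without E93RNAi+brRNAi 44 h replicate 3, ribosomal genes risen in E93RNAi+brRNAi at 44 h went from 2 to 1 against control and against E93RNAi, and respiratory genes risen against E93RNAi from 8 to 5. In the smaller direction, respiratory genes risen against control at 44 h went from 6 to 3 without that library. Low counts limit genes such as Brd and msd1.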

Other observations

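The tests of label exchange and hairpin reads, of a transgene and of br for Dcr-2, and of developmental stage were chosen after the results were seen, and the test of the Dcr-2 neighbourhood before.

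Planar polarity, autophagy, cell death and JNK, glia and trachea lists did not pass camera in any of the 6 genotype comparisons or in the control time change, and of these comparisons hemocyte markers passed only in the control time change (adjusted p = 0.0329). Of 10 planar polarity genes, 5 rose in E93RNAi against control at 24 h (adjusted p = 0.307), or 2 without E93RNAi 24 h replicate 3, for example fj, which tunes Fat and Dachsous binding (0.22 ± 0.05), and 2 rose and 5 fell at 44 h (adjusted p = 0.236), with Vang, a core polarity gene, at 280 ± 5.79 against 339 ± 7.96 CPM. Of 17 autophagy genes 1 rose and 1 fell in E93RNAi against control at 44 h (adjusted p = 0.591). Cell death and JNK genes had 12 risen and 4 fallen of 26 there (adjusted p = 0.0505), where the TNF receptor gene wgn fell from 385 ± 11.8 to 146 ± 4.20 CPM, and scaf rose from 46.8 ± 2.04 to 178.5 ± 16.02 CPM. In control wings wgn rose from 72.6 ± 0.663 CPM at 24 h and scaf fell from 254 ± 7.95 CPM.

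Glia markers had 3 risen and 4 fallen of 10 in E93RNAi against control at 44 h (adjusted p = 0.808), with Gli at 185 ± 5.61 against 125 ± 4.82 CPM. Trachea markers had 7 risen and 2 fallen of 11 (adjusted p = 0.0613), among them the apical polarity gene crb, also expressed in wing epithelium (286 ± 29.2 to 475 ± 41.7 CPM). Hemocyte markers had 2 risen and 7 fallen of 16 (adjusted p = 0.0792), led by NimC2 (34.3 ± 1.66 to 16.3 ± 1.17 CPM).

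Eip93F transcript was not lower in the 24 h libraries labelled E93RNAi, while br was 2.68 log2 units higher, and at 44 h Eip93F was at 1113 to 1182 CPM in E93RNAi and 1243 to 1337 CPM in control (log2 fold change -0.15, adjusted p = 0.0522, called under 7 other settings). An exchange of control and E93RNAi labels cannot be told apart from correct labels by this gene, since the log2 fold change was -0.008 with a 95% interval from -0.13 to 0.12, so that Eip93F was lower in neither group at 24 h, and the 44 h values ran the way the labels say by a small amount only. Reads from the RNAi hairpin could mask a loss of messenger RNA, since they may fall in the counted transcript. In E93RNAi+brRNAi the log2 fold change against control at 24 h was 0.19, and totals per gene cannot tell such reads apart from the endogenous transcript. RNAi that lowers the protein without lowering the counted transcript stays open as well and was not tested.

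Dcr-2 was the gene with rank 7 by level in the 24 h E93RNAi libraries, and was high in the libraries labelled E93RNAi at both times but not in those labelled E93RNAi+brRNAi. A regional change around its locus is argued against by the 20 other tested genes within 50000 bases, whose median log2 fold change at 24 h was 0.005, from -0.77 to 0.89. A transgene that the labels do not name may be present in the E93RNAi flies: the rise was 5.13 at 44 h and present in every library, and w, a common transgene marker chosen after its values were seen, was at 698.7 to 735.7 CPM in E93RNAi at 24 h, 315.4 to 320.4 in control and 369.7 to 419.1 in E93RNAi+brRNAi. A rise of the endogenous gene that depends on br cannot be told apart from it, since Dcr-2 fell with br (-5.30 at 24 h) and genotype and any transgene go together in this design. At 44 h, however, br stayed above control in E93RNAi+brRNAi (2.14) while Dcr-2 did not (-0.27).

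Changed genes (log2 fold change of at least 1 either way) that were also called in the control time change were compared with its direction. At 24 h, 445 of 531 (83.8%) moved with it in E93RNAi+brRNAi against control and 477 of 644 (74.1%) in E93RNAi against control. Simulation without any effect, with shared controls and as many genes of smallest p, gave medians of 56.3% and 55.8% over 9 draws. At 44 h, 342 of 760 (45%) moved with it in E93RNAi+brRNAi and 271 of 903 (30%) in E93RNAi, against simulated medians of 43.1% and 43.2%. The E93RNAi changes at 44 h thus ran mostly against the control time change, and the share in E93RNAi+brRNAi at 44 h lay within the simulated range (41.7% to 45.9%).

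The 24 h libraries labelled E93RNAi+brRNAi lay nearer to the 44 h libraries on the first principal component than control did, at -52.14 to -46.52 against -73.94 to -71.5, with E93RNAi at -63.76 to -62.03. At 44 h E93RNAi+brRNAi lay further along this component as well, at 75.86 to 79.93 against 56.32 to 58.13 in control. There E93RNAi lay at 49.17 to 52.8. Wings that were collected or developed later could give this pattern. At 24 h, 83.8% of the 531 genes moved with the control time change, more than without any effect (56.3%), whereas at 44 h the share was 45%. The bound for that explanation at 24 h, set after the results were seen, was over 95% of the 673 changed genes within the range of the control groups. Outside it by at least 1 log2 unit lay 38.6% (260 genes, 46 of them above). A later stage would account for those genes only if they peak or dip between the times, so the test does not decide. No control library lies between 24 h and 44 h, so a later stage and an effect of the RNAi transgenes cannot be told apart for the rest either. None lies after 44 h, so a later stage of the 44 h E93RNAi+brRNAi libraries was not tested.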
